A study of Mus musculus with 11 samples.

How the data were processed

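The data are gene-level RNA-seq counts of 11 libraries from mouse large-intestinal ILC2s. Per the labels' protocols, the sorted cells were cultured for 3 h in medium that held IL-2 and IL-7 at 100 ng/ml each, and IL-25 (100 ng/ml) or ADM2 (0.4 µg/ml) where the group had it. RNA was isolated with the PicoPure kit, and libraries made by Novogene were sequenced as 150 bp paired-end reads. The deposited values are raw read counts per gene, whole numbers keyed by Entrez Gene ID, in 1 table of 27179 genes and 11 libraries. Per the submitters' processing notes, featureCounts, limma and the mm10 build were used, with no versions or roles. The aligner, the annotation release and whether counting used strand are not given in the sources used here, so values of overlapping and antisense genes, and of near-identical paralogs, are uncertain. Among the named genes Crem, Csf2, Ramp3, Tagap, Gata3, Il6, Coro2a, Trim14, Snx30, Nfic, Vldlr, Pdgfb and Focad overlap other annotated genes, most of them predicted or of microRNAs.

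Symbols and mm10 coordinates came from a RefSeq gene table of assembly GRCm38.p6, which matched 25275 IDs and left 1904 unmatched. Unmatched IDs held 1.16% to 2.68% of the counts per library, and were kept in the tests under their IDs. Each library's group came from its sample title. IL-25 plus ADM2 replicates 2 and 3 were used, and a replicate 1 of that group was not analysed here. Total counts were 25809256 to 35445351 per library, and the 5 most abundant genes (IDs 100861531 and 319269, Eef1a1, COX1 and H2-K1) took 2.42% to 4.21%, mitochondrial transcripts 1.23% to 1.54%. TMM factors were 1.09 to 1.12 for vehicle, 1.01 to 1.02 for ADM2, 0.935 to 0.947 for IL-25 and 0.904 to 0.933 for IL-25 plus ADM2. No 2 libraries of a group looked like copies of each other: the chi-square of their counts per degree of freedom was 16.6 to 58.1 over the 10 pairs of libraries of the same group.

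Counts were tested with edgeR 4.0.16 in R 4.3.3 (TMM factors, filterByExpr with a minimum count of 10, which kept 15028 genes, quasi-likelihood F test with 1 mean per group fitted over all 11 libraries). The common biological coefficient of variation was 0.282 and the median over genes 0.176. A gene was called at a Benjamini-Hochberg adjusted p below 0.05. The 6 contrasts were: the ADM2 effect without IL-25, the IL-25 effect, the ADM2 effect with IL-25, both against vehicle, the ADM2 effect averaged over both backgrounds, and the difference of the ADM2 effect between them. Levels are normalised counts (CPM, from library sizes multiplied by their TMM factors), as mean ± SD, and log2 fold changes are given ± SE. This SE is the absolute log2 fold change divided by the square root of its F value, so it is approximate. The test was checked on counts simulated from the real means and library sizes, in 5 simulations of 15028 genes with 200 changed genes each. For ADM2 versus vehicle 60.6% of genes changed by 2-fold and 28.4% of those changed by 1.5-fold were recovered, for IL-25 plus ADM2 versus IL-25 48.2% and 15.2%, and for the difference of the ADM2 effect 32.8% and 4%. Unchanged genes made up 7.10%, 8.38% and 9.80% of the calls in those comparisons, above the nominal 5% set by the threshold. The data had 2227 calls in ADM2 versus vehicle and 2198 in IL-25 plus ADM2 versus IL-25, more than the 200 genes changed here. The adjusted threshold then admits larger p-values, so recovered and false shares there may differ from these.

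Lists of 20 gene groups and 9 cell types, the comparisons, the tests and the naming rule were fixed before the data were examined. Lists were tested with camera (limma 3.58.1) at its preset correlation of 0.01, with Benjamini-Hochberg adjustment within a comparison, and again with an estimated correlation and with fry. Lists with fewer than 3 tested members had no set test. Named genes were: the 10 largest increases and 10 largest decreases past the threshold with a mean of at least 2 log2 CPM and no overlap between the libraries of the groups (no overlap rule for the averaged and the difference contrast), leaving out predicted genes, IDs without a symbol and antigen receptor segments, or the 5 smallest p-values where fewer than 5 genes passed. Also named were 11 genes whatever their result (Areg, Il5, Il13, Calcrl, Ramp1, Ramp3, Il17rb, Il1rl1, Gata3, Crem and Nr4a1), at most 4 members per list, those past the threshold with the smallest p or otherwise the smallest p, and the 5 most abundant genes. Several genes stand in more than 1 list, such as Il22 in the repair and ILC3 lists. Areg, Hbegf, Il10, Il9, Penk and Lif stand in both the type 2 cytokine and the repair list, so calls of these lists are not independent. Results for some genes, and a test of ILC3 RNA as the source of Il17a and Il17f, are not reported here.

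Alternatives were DESeq2 1.42.0, limma voom without and with sample quality weights, median-ratio and upper-quartile scaling, no filter on low counts, a minimum count of 30, only the groups compared, the replicate number as a block, a change of at least 2-fold, and each library left out in turn. Added after seeing the data were fits without the 169 immunoglobulin genes tested and the agreement over genes of at least 2 log2 CPM. Overlaps of comparisons that share the vehicle libraries were set beside 20 simulations of groups with no effect.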

Results

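Group 2 innate lymphoid cells (ILC2s) are tissue-resident lymphocytes that secrete IL-5, IL-13 and the epidermal growth factor family member amphiregulin. They were sorted from the large intestine of wild-type C57BL/6 mice and cultured for 3 h with IL-2 and IL-7. ADM2 (adrenomedullin 2, also called intermedin) is a peptide of the calcitonin gene-related peptide (CGRP) family that signals through the receptor CALCRL paired with a RAMP protein. IL-25 is an epithelial alarmin that activates ILC2s through the receptor subunit IL-17RB. The series title names tissue-protective responses of ILC2s to ADM2 and intestinal inflammation as its subject. The 4 groups ask what ADM2 changes in cells cultured in IL-2 and IL-7, without and with IL-25. RNA from 11 cultures was sequenced: vehicle (n = 3), 0.4 µg/ml ADM2 (n = 3), 100 ng/ml IL-25 (n = 3), and IL-25 plus ADM2 at those doses (n = 2). Total counts ran from 25809256 (IL-25 replicate 1) to 35445351 (ADM2 replicate 3), and 14837 to 15954 genes had at least 1 count. The labels do not say whether replicates came from separate mice, so p-values measure only the spread between these samples, which may be technical.

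ADM2 alone raised transcripts of several ILC2 cytokines and of cAMP-responsive genes within 3 h and lowered those of ribosome biogenesis. Il5 (Entrez ID 16191, chromosome 11, 53720794 to 53725103, mm10) rose 3.69-fold, from 554 ± 51.9 to 2043 ± 84.0 CPM (SD, n = 3 each; edgeR adjusted p = 8.69e-09). Areg (Entrez ID 11839, chromosome 5, 91139599 to 91148432), which encodes amphiregulin, rose 2.91-fold, from 65.0 ± 5.70 to 189 ± 17.6 CPM (edgeR adjusted p = 2.30e-07). Il13 (Entrez ID 16163, chromosome 11, 53631323 to 53634702) moved the other way and fell 1.95-fold, from 281 ± 18.0 to 144 ± 11.02 CPM (edgeR adjusted p = 2.42e-06). Il9 rose from 73.4 ± 4.29 to 219.9 ± 46.8 CPM, and Il2, a T cell growth factor, from 4.58 ± 1.44 to 28.8 ± 5.70 CPM.

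Of 15028 genes tested, ADM2 changed 2227 (edgeR quasi-likelihood test, Benjamini-Hochberg adjusted p below 0.05), 1111 higher and 1116 lower. A change of at least 2-fold was seen for 481 of these, 291 higher and 190 lower. Among the largest increases by the naming rule were Tgm2, which encodes transglutaminase 2 (chromosome 2, 158116405 to 158146392; log2 fold change 3.64 ± 0.09, SE; 121 ± 5.27 to 1505 ± 123 CPM), and Csf2rb2 (3.62 ± 0.12). Reads of Csf2rb2 can be split with its near-identical neighbour Csf2rb, so that either value is uncertain. Others among them were Mir1938 (3.42 ± 0.50), Ncald (3.15 ± 0.25) and the transcription factor gene Hhex (2.93 ± 0.27), as well as Dppa2 (2.82 ± 0.37), Il2 (2.65 ± 0.28), Fndc4 (2.60 ± 0.43) and Il17f (2.56 ± 0.16). The largest decreases were Pcsk4 (−2.43 ± 0.34), the transcription factor gene Tfap4 (−2.32 ± 0.20), Nkain1 (−2.26 ± 0.41), Pdgfb (−2.15 ± 0.37) and Nhlrc1 (−2.14 ± 0.38). Further decreases were Shmt1 (−2.11 ± 0.14), Dleu2 (−2.09 ± 0.25), Sema3e (−1.92 ± 0.27), the reduced folate carrier gene Slc19a1 (−1.89 ± 0.13) and Dnah12 (−1.81 ± 0.11). Mir1938 lies inside Ifrd1 and cannot be told from it without strand or size selection. Dleu2 overlaps Trim13, Kcnrg and microRNA genes, and Ncald and Dnah12 overlap predicted genes, so these values are uncertain where the counting did not use strand.

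Genes induced by cAMP and CREB, the signalling route of Gs-coupled receptors, moved mostly 1 way with ADM2: 20 of 25 members rose and 0 fell, or 20 and 1 adjusted over the list alone (camera adjusted p = 1.55e-30). Crem, a cAMP-induced transcription factor gene, rose 3.41-fold, from 292 ± 29.5 to 995 ± 69.7 CPM. Ptgs2 (cyclooxygenase 2) rose 2.68-fold, Rgs2 2.95-fold and Nr4a1 1.51-fold (edgeR adjusted p = 0.00162 for Nr4a1). In the MYC and ribosome biogenesis list 1 of 26 members rose and 23 fell, or 1 and 25 adjusted over the list alone (camera adjusted p = 1.92e-25). Rrp12 (−1.46 ± 0.13), Polr1b (−1.40 ± 0.11), which encodes a subunit of RNA polymerase I, and Dkc1 (−1.34 ± 0.11) fell. The member that rose was Odc1 (1.67 ± 0.08), the rate-limiting enzyme of polyamine synthesis. Among type 2 cytokines and growth factors 14 of 25 members rose and 2 fell, or 14 and 2 adjusted over the list alone (camera adjusted p = 9.37e-11). In tissue protection and repair 11 of 22 members rose and 1 fell, or 11 and 2 adjusted over the list alone (camera adjusted p = 3.91e-08), and Furin (0.97 ± 0.12) and Osm (0.89 ± 0.09) were among those that rose.

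Among ILC2 identity and receptor genes 9 of 26 members rose and 3 fell, or 12 and 3 adjusted over the list alone (camera adjusted p = 0.00154) in ADM2 versus vehicle. Il1rl1, the IL-33 receptor gene (chromosome 1, 40404864 to 40465418), rose 1.997-fold, Il17rb, the IL-25 receptor subunit gene (chromosome 14, 29996168 to 30008896), 1.59-fold and Rora 2.60-fold, whereas Gfi1 fell 1.963-fold. Among co-stimulatory and inhibitory receptors 8 of 19 members rose and 1 fell, or 8 and 1 adjusted over the list alone (camera adjusted p = 1.08e-05). Pdcd1, which encodes PD-1, rose 3.24-fold and Tnfrsf18 (GITR) 2.34-fold, and Tnfsf4 (OX40 ligand) fell 2.15-fold. Among glycolysis and hypoxia genes 9 of 24 members rose and 0 fell, or 11 and 0 adjusted over the list alone (camera adjusted p = 2.77e-06), led by Egln3, a prolyl hydroxylase of HIF (2.08 ± 0.08), and Hif1a (1.11 ± 0.08). The calls of cAMP, MYC, cytokine, repair, identity, co-stimulatory and glycolysis genes held with an estimated correlation (adjusted p from 0.00164 to 0.0281).

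In the CGRP family 3 of 8 members rose and 0 fell, or 3 and 1 adjusted over the list alone (camera adjusted p = 0.0127, or 0.184 with an estimated correlation) in ADM2 versus vehicle. Ramp3 (chromosome 11, 6658506 to 6677478), a partner of CALCRL whose locus overlaps a predicted gene, rose 2.60-fold, from 715 ± 65.9 to 1856 ± 139 CPM. Calca, which encodes CGRP, rose from 499 ± 80.6 to 987 ± 101.2 CPM. Calcrl was at 42.7 ± 3.46 and 31.6 ± 5.03 CPM (edgeR adjusted p = 0.0547). Ramp1 was at 11.7 ± 1.24 and 10.3 ± 1.08 CPM (edgeR adjusted p = 0.693) and Gata3 at 936 ± 39.8 and 1218 ± 24.3 CPM (edgeR adjusted p = 0.0567). None of these differences passed the edgeR test at its first settings (TMM factors, minimum count of 10) with every library. Calcrl passed it without vehicle replicate 1 (edgeR adjusted p = 0.0494), ADM2 replicate 3 (0.0290) or IL-25 replicate 1 (0.0291), and Gata3 without IL-25 replicate 1 (0.00142) or 2 (0.0266). With every library kept, both passed with DESeq2 (adjusted p = 0.0256 for Calcrl and 0.0170 for Gata3), limma voom (0.0398 and 0.0378), sample quality weights (0.0349 and 0.00946) and no filter on low counts (0.0285 and 0.0277). Gata3 passed also with upper-quartile factors (0.0401) and a minimum count of 30 (0.0487), so for both genes the outcome depends on the method.

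Other calls in ADM2 versus vehicle were lost with an estimated correlation. Among immediate early genes 13 of 24 members rose and 1 fell, or 16 and 2 adjusted over the list alone (camera adjusted p = 1.50e-11, or 0.120 with an estimated correlation), including Fosb (1.51 ± 0.16) and Fos (0.96 ± 0.09). In the unfolded protein and integrated stress response 14 of 24 members rose and 3 fell, or 15 and 3 adjusted over the list alone (camera adjusted p = 2.27e-06, or 0.120 with an estimated correlation). The chaperone genes Dnajb9 (1.01 ± 0.10) and Hspa5 (0.90 ± 0.09) rose, and Shmt2 (−0.93 ± 0.11), a mitochondrial serine hydroxymethyltransferase gene, fell. In migration and residency 8 of 21 members rose and 0 fell, or 8 and 0 adjusted over the list alone (camera adjusted p = 2.45e-04, or 0.0928 with an estimated correlation), with the chemokine receptor genes Ccr8 (1.24 ± 0.11) and Cxcr4 (1.19 ± 0.13) among them. Among NF-kB targets 8 of 27 members rose and 3 fell, or 10 and 5 adjusted over the list alone (camera adjusted p = 0.0244, or 0.405 with an estimated correlation). This call was lost without vehicle replicate 3 or ADM2 replicate 3 (camera adjusted p up to 0.0910). Among STAT5 and cytokine feedback genes 7 of 18 members rose and 4 fell, or 10 and 4 adjusted over the list alone (camera adjusted p = 0.0430, or 0.405 with an estimated correlation). This call was lost without vehicle replicate 1, vehicle replicate 2, vehicle replicate 3, ADM2 replicate 1, ADM2 replicate 3, IL-25 replicate 1 or IL-25 replicate 2 (camera adjusted p up to 0.0954), and with the replicate block (0.0724). Among cytosolic ribosomal proteins 1 of 31 members rose and 0 fell, or 0 and 0 adjusted over the list alone (camera adjusted p = 0.00449, or 0.602 with an estimated correlation). This call was lost without vehicle replicate 1 or ADM2 replicate 1 (camera adjusted p up to 0.0779). Cholesterol synthesis, other neural and lipid mediator receptors, cell cycle, interferon-stimulated genes, heat shock and oxidative phosphorylation were not called (camera adjusted p from 0.250 to 0.471).

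**Figure D1:**
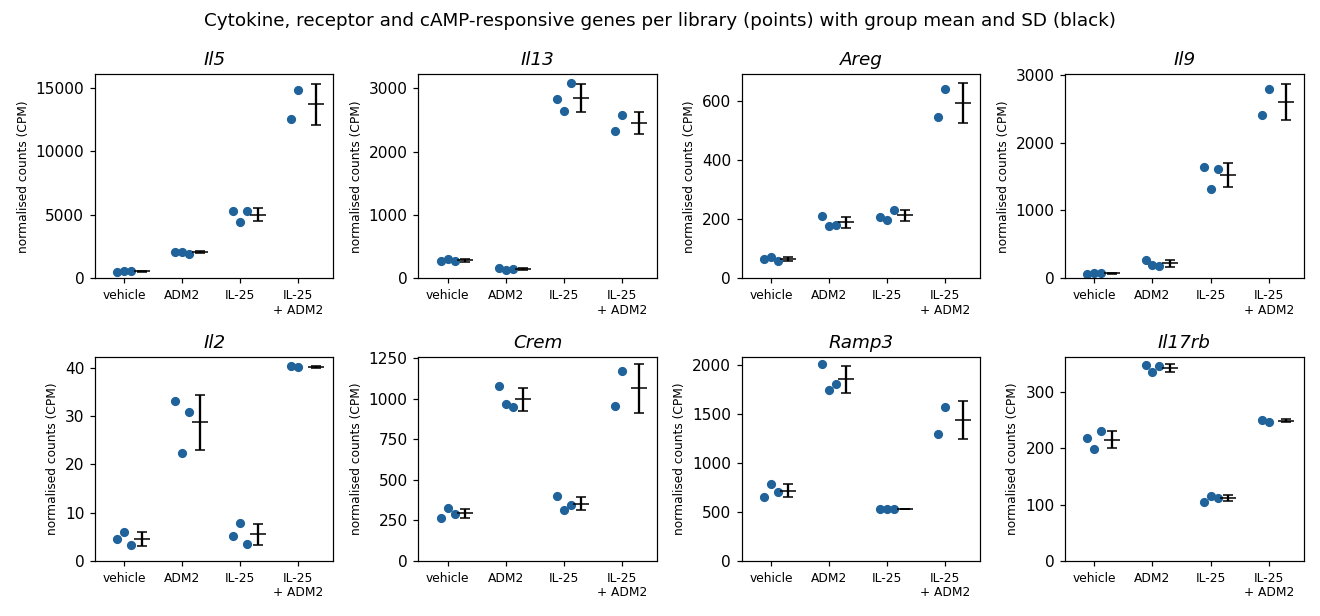
Normalised counts (CPM, linear axes from 0) of 8 genes in the vehicle, ADM2, IL-25 and IL-25 plus ADM2 groups, with 1 point per library and the group mean and SD in black. Il5 averaged 554, 2043, 5013 and 13699 CPM in that order, whereas Il13 was lower with ADM2 alone (144 against 281 CPM).

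IL-25 alone raised the effector cytokines of ILC2s, NF-kB targets and ribosome biogenesis genes. Il13 rose 10.1-fold (to 2852 ± 217 CPM), Il5 9.04-fold (to 5013 ± 499.9 CPM), Il9 20.8-fold (to 1524 ± 179 CPM), Il6 16.5-fold (to 1097 ± 48.0 CPM) and Csf2, which encodes GM-CSF, 7.09-fold (to 1483 ± 111 CPM; n = 3). Areg rose 3.27-fold, to 213 ± 17.7 CPM. The IL-25 receptor gene Il17rb fell 1.94-fold, from 216 ± 15.7 to 111 ± 5.37 CPM (edgeR adjusted p = 2.13e-06), and Ramp3 fell 1.35-fold (edgeR adjusted p = 0.00324). Calcrl (0.04 ± 0.14), Ramp1 (−0.58 ± 0.23), Gata3 (0.02 ± 0.13) and Crem (0.27 ± 0.11) had log2 fold changes that did not pass the test (edgeR adjusted p from 0.0883 to 0.927), though Ramp1 did without IL-25 replicate 1 (0.0108), with limma voom (0.0403) and with sample quality weights (0.0182), and Crem without IL-25 replicate 2 (0.0475). Nr4a1 (1.07 ± 0.11) and Il1rl1 (0.54 ± 0.07) rose.

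IL-25 changed 3503 genes, 1947 higher and 1556 lower, of which 672 by at least 2-fold (250 higher and 422 lower). The share of calls that were higher was 55.6% with TMM scaling and 44.6% with upper-quartile factors. Besides Il9 and Il6 the largest increases included the hepcidin gene Hamp (4.44 ± 0.29; its paralog Hamp2 can share reads), the NF-kB regulator gene Tnip3 (4.16 ± 0.22), Il17f (3.63 ± 0.17), Il24 (3.15 ± 0.22) and Dgat2 (2.59 ± 0.09), an enzyme of triglyceride synthesis. Decreases were led by Paqr7 (−2.56 ± 0.25), Nynrin (−2.41 ± 0.31), Sla2 (−2.37 ± 0.23) and the cannabinoid receptor gene Cnr2 (−2.17 ± 0.28). Next came the lysophosphatidic acid receptor gene Lpar5 (−2.07 ± 0.31), Cbx8 (−2.06 ± 0.31), Zfp658 (−2.01 ± 0.31), Chst2 (−2.01 ± 0.17) and Snx30 (−1.98 ± 0.19).

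In the type 2 cytokine list 15 of 25 members rose and 0 fell, or 16 and 0 adjusted over the list alone (camera adjusted p = 1.09e-41) with IL-25. In tissue protection and repair 10 of 22 members rose and 0 fell, or 10 and 0 adjusted over the list alone (camera adjusted p = 4.93e-12), including Il22 (2.46 ± 0.12) and Hbegf (1.05 ± 0.11). Among NF-kB targets 23 of 27 members rose and 0 fell, or 25 and 0 adjusted over the list alone (camera adjusted p = 2.55e-30), including Cd83 (2.27 ± 0.14) and Birc3 (1.02 ± 0.08). In MYC and ribosome biogenesis 25 of 26 members rose and 0 fell, or 26 and 0 adjusted over the list alone (camera adjusted p = 1.48e-34), including Myc (1.44 ± 0.09), Rrp9 (1.21 ± 0.10) and Wdr43 (1.13 ± 0.09). These 4 calls held with an estimated correlation (adjusted p from 2.88e-04 to 0.00346).

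The other calls in IL-25 versus vehicle were lost with an estimated correlation. Among STAT5 and cytokine feedback genes 11 of 18 members rose and 3 fell, or 12 and 3 adjusted over the list alone (camera adjusted p = 7.33e-08, or 0.0579 with an estimated correlation). In heat shock and dissociation stress 9 of 15 members rose and 0 fell, or 9 and 0 adjusted over the list alone (camera adjusted p = 5.38e-06, or 0.0579 with an estimated correlation). Among immediate early genes 12 of 24 members rose and 1 fell, or 13 and 1 adjusted over the list alone (camera adjusted p = 1.50e-06, or 0.334 with an estimated correlation). In the unfolded protein and integrated stress response 14 of 24 members rose and 0 fell, or 17 and 1 adjusted over the list alone (camera adjusted p = 1.29e-05, or 0.197 with an estimated correlation). In cholesterol synthesis 8 of 24 members rose and 1 fell, or 9 and 1 adjusted over the list alone (camera adjusted p = 0.00313, or 0.187 with an estimated correlation). Among cytosolic ribosomal proteins 10 of 31 members rose and 0 fell, or 16 and 0 adjusted over the list alone (camera adjusted p = 3.73e-04, or 0.695 with an estimated correlation). Among interferon-stimulated genes 0 of 26 members rose and 5 fell, or 0 and 3 adjusted over the list alone (camera adjusted p = 0.0315, or 0.695 with an estimated correlation). This call was lost without vehicle replicate 3 or IL-25 replicate 3 (camera adjusted p up to 0.178). Lists of cAMP and CREB, ILC2 identity, migration, co-stimulatory receptors, glycolysis, the CGRP family, other neural receptors, cell cycle and oxidative phosphorylation were not called (camera adjusted p from 0.159 to 0.861).

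Added to IL-25, ADM2 again raised Il5, Areg and the cAMP-responsive genes and lowered ribosome biogenesis genes. Il5 rose 2.73-fold, from 5013 ± 499.9 (SD, n = 3) to 13699 ± 1641 CPM (n = 2; edgeR adjusted p = 4.15e-07). Areg rose 2.79-fold to 593 ± 68.2 CPM (edgeR adjusted p = 1.26e-06) and Il9 1.70-fold to 2598 ± 271 CPM (edgeR adjusted p = 0.00182). Il13 was at 2852 ± 217 CPM with IL-25 and 2455 ± 174 CPM with both (log2 fold change −0.22 ± 0.10; edgeR adjusted p = 0.166), which did not pass the test. Crem rose 3.01-fold, Ramp3 2.72-fold, Il17rb 2.24-fold (111 ± 5.37 to 249 ± 2.25 CPM) and Il1rl1 1.71-fold. Gata3 rose by a log2 fold change of 0.49 ± 0.14 (edgeR adjusted p = 0.0266) and Calcrl fell (−0.62 ± 0.16; 0.0176). Both calls were lost without IL-25 plus ADM2 replicate 2 (edgeR adjusted p = 0.141 and 0.0878) or 3 (0.0918 and 0.113), and that of Calcrl also without IL-25 replicate 1 (0.0557). That of Gata3 was lost also with the replicate block (0.0629). Ramp1 (0.30 ± 0.26; edgeR adjusted p = 0.517) and Nr4a1 (0.72 ± 0.12; 8.84e-04) were tested alongside.

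In the IL-25 background ADM2 changed 2198 genes, 981 higher and 1217 lower, and 499 of them by at least 2-fold (322 higher and 177 lower). With 2 libraries in 1 group the count was 1323 without IL-25 plus ADM2 replicate 2 and 1275 without replicate 3, and the higher calls made up 44.6% with TMM and 57.4% with upper-quartile factors. Among the largest increases by the naming rule were Csf2rb2 (3.16 ± 0.13), Il2 (2.87 ± 0.29), Tgm2 (2.87 ± 0.09) and Hhex (2.83 ± 0.29), as well as Mir1938 (2.83 ± 0.52), Ncald (2.79 ± 0.26), Il17a (2.59 ± 0.38), the lipoprotein receptor gene Vldlr (2.48 ± 0.40) and Csf2rb (2.45 ± 0.22). The largest decreases were Dnah12 (−2.84 ± 0.13), Klrg2 (−1.92 ± 0.26), the deoxycytidylate deaminase gene Dctd (−1.89 ± 0.18), Sema3e (−1.86 ± 0.32), Slc19a1 (−1.75 ± 0.15), Shmt1 (−1.73 ± 0.15) and Focad (−1.72 ± 0.33). Nkain1 (−1.90 ± 0.46), Pdgfb (−1.88 ± 0.42) and Egr4 (−1.80 ± 0.56) were also among the 10, but lost their calls without IL-25 plus ADM2 replicate 3 (edgeR adjusted p = 0.133, 0.0666 and 0.144). The call of Egr4 was lost also without vehicle replicate 2, ADM2 replicate 1, IL-25 replicate 2 or 3, or IL-25 plus ADM2 replicate 2, and with limma voom (adjusted p = 0.0995) or sample quality weights (0.0693).

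In the cAMP and CREB list 18 of 25 members rose and 0 fell, or 19 and 0 adjusted over the list alone (camera adjusted p = 8.52e-31) in IL-25 plus ADM2 versus IL-25, with Ptgs2 up 4.13-fold and Rgs2 up 2.54-fold. In MYC and ribosome biogenesis 1 of 26 members rose and 23 fell, or 1 and 25 adjusted over the list alone (camera adjusted p = 1.99e-21). Utp20 (−1.60 ± 0.14) and Wdr12 (−1.17 ± 0.13) fell and Odc1 (1.76 ± 0.09) rose. Among type 2 cytokines 13 of 25 members rose and 1 fell, or 15 and 1 adjusted over the list alone (camera adjusted p = 2.02e-12). In tissue protection and repair 9 of 22 members rose and 1 fell, or 9 and 2 adjusted over the list alone (camera adjusted p = 1.06e-04), including Hmox1 (0.66 ± 0.12). Among ILC2 identity genes 11 of 26 members rose and 1 fell, or 12 and 2 adjusted over the list alone (camera adjusted p = 2.08e-04), with Hey1 (1.47 ± 0.24) higher. Among co-stimulatory and inhibitory receptors 6 of 19 members rose and 1 fell, or 9 and 2 adjusted over the list alone (camera adjusted p = 2.52e-05), with Pdcd1 (1.60 ± 0.10) higher and Tnfsf4 (−1.55 ± 0.16) lower. These 6 calls held with an estimated correlation (adjusted p from 0.00224 to 0.0219).

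The other calls in IL-25 plus ADM2 versus IL-25 were lost with an estimated correlation. Among immediate early genes 16 of 24 members rose and 1 fell, or 16 and 1 adjusted over the list alone (camera adjusted p = 8.69e-12, or 0.117 with an estimated correlation), including Fosb (1.69 ± 0.18). In migration and residency 9 of 21 members rose and 1 fell, or 9 and 1 adjusted over the list alone (camera adjusted p = 4.46e-04, or 0.100 with an estimated correlation), including Ccr8 (1.31 ± 0.12). In cholesterol synthesis 0 of 24 members rose and 5 fell, or 0 and 11 adjusted over the list alone (camera adjusted p = 5.01e-04, or 0.100 with an estimated correlation). Sqle (−0.72 ± 0.12) was lower. In the unfolded protein and integrated stress response 11 of 24 members rose and 4 fell, or 13 and 4 adjusted over the list alone (camera adjusted p = 0.00162, or 0.249 with an estimated correlation). In glycolysis and hypoxia 5 of 24 members rose and 0 fell, or 5 and 1 adjusted over the list alone (camera adjusted p = 0.00451, or 0.117 with an estimated correlation), including Egln3 (2.06 ± 0.09). In the CGRP family 3 of 8 members rose and 1 fell, or 3 and 1 adjusted over the list alone (camera adjusted p = 0.00532, or 0.130 with an estimated correlation), including Calca (1.11 ± 0.14). Among STAT5 and cytokine feedback genes 7 of 18 members rose and 3 fell, or 9 and 3 adjusted over the list alone (camera adjusted p = 0.00568, or 0.1996 with an estimated correlation). This call was lost without IL-25 replicate 1 (camera adjusted p = 0.0731). NF-kB targets, other neural receptors, interferon-stimulated genes, cytosolic ribosomal proteins, cell cycle, heat shock and oxidative phosphorylation were not called (camera adjusted p from 0.0574 to 0.803).

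**Figure D2:**
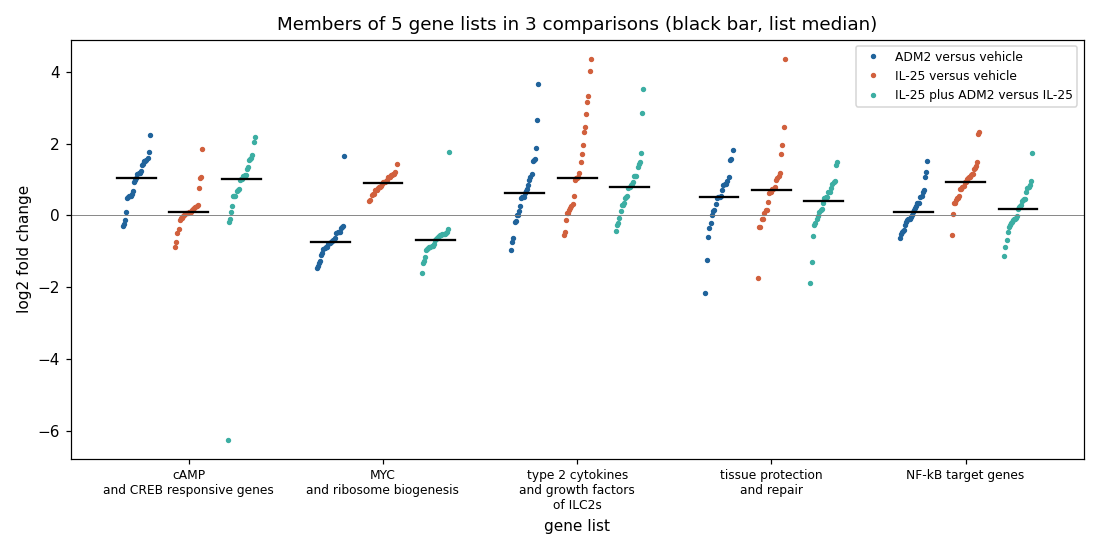
Log2 fold changes (vertical axis) of the members of 5 gene lists in ADM2 versus vehicle, IL-25 versus vehicle and IL-25 plus ADM2 versus IL-25, with 1 point per gene and the list median as a black bar. MYC and ribosome biogenesis genes had medians of −0.75, 0.90 and −0.68, and cAMP and CREB genes 1.03, 0.09 and 1.01, in that order.

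With both stimuli, Il5 reached 24.7-fold its vehicle level, Il9 35.4-fold, the chemokine gene Cxcl2 17.0-fold and Ptgs2 14.8-fold. Il17f rose from 3.89 ± 1.11 to 193 ± 12.6 CPM and Il17a from 1.21 ± 0.465 to 29.1 ± 9.23 CPM. In IL-25 plus ADM2 versus vehicle 3042 genes changed, 1593 higher and 1449 lower, 835 of them by at least 2-fold, and 1695 changed without IL-25 plus ADM2 replicate 3. Il24 (3.66 ± 0.24) and Hamp (4.56 ± 0.30) were among the largest increases. Chst2 (−2.39 ± 0.20), Nfic (−2.38 ± 0.28), Tnfrsf26 (−2.24 ± 0.17), Trim14 (−2.14 ± 0.24), Coro2a (−1.98 ± 0.13) and Sigirr (−1.92 ± 0.16), an inhibitory receptor of the IL-1 family, were among the largest decreases. Il17rb, lowered by IL-25 and raised by ADM2, was at 249 ± 2.25 CPM against 216 ± 15.7 in vehicle (log2 fold change 0.21 ± 0.09; edgeR adjusted p = 0.144). The type 2 cytokine list had 21 of 25 members higher (camera adjusted p = 2.98e-75; adjusted p = 4.06e-04 with an estimated correlation). The MYC and ribosome biogenesis list had 7 higher and 3 lower of 26 (camera adjusted p = 0.00488; adjusted p = 0.0785 with an estimated correlation). In all, 16 of 20 lists were called and 10 with an estimated correlation. For migration and residency the median (−0.01) and the test, which called the list higher (camera adjusted p = 2.77e-04; adjusted p = 0.0692 with an estimated correlation), differed in sign.

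Averaged over both backgrounds, 5 libraries with ADM2 against 6 without, ADM2 changed 3708 genes, 1674 higher and 2034 lower, 570 by at least 2-fold. The higher calls made up 45.1% with TMM and 53.3% with upper-quartile factors, so which direction holds more genes depends on the scaling. Il5 (1.67 ± 0.07), Areg (1.51 ± 0.08), Crem (1.68 ± 0.08), Ramp3 (1.41 ± 0.07), Il17rb (0.92 ± 0.06), Il1rl1 (0.89 ± 0.06), Nr4a1 (0.65 ± 0.08) and Gata3 (0.44 ± 0.09) rose on average. Il13 (−0.59 ± 0.07) and Calcrl (−0.53 ± 0.11) fell, and Ramp1 (0.06 ± 0.17) was not called (edgeR adjusted p = 0.861). The effects in the backgrounds, which share no library, ran alike: of the 2227 genes called in ADM2 versus vehicle, 2181 (97.9%) had the same sign in IL-25 plus ADM2 versus IL-25, against 10514 (70.0%) of all 15028 genes tested. Both comparisons called 687 genes as higher, where independent lists would share 72.5, and 734 as lower against 90.4, while 4 were called in opposite directions. Across all 15028 genes, which are not independent replicates, Pearson's r was 0.22 and Spearman's rho 0.45, and r was 0.63 and rho 0.72 over the 9864 genes with an average of at least 2 log2 CPM.

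The test of the difference of the ADM2 effect between backgrounds called 5 genes by edgeR (1028 at an unadjusted p below 0.05). Among them were Tagap and Dnah12 under the naming rule, and the immunoglobulin segments Ighv1-19 and Igkv17-127, named here after their values were seen. DESeq2 called 47 and limma voom 1. The count was 2 without vehicle replicate 1, 3 without vehicle replicate 3, 2 without ADM2 replicate 1, 1 without ADM2 replicate 2 or 3, 0 without IL-25 replicate 2 or 3, and 1 without IL-25 plus ADM2 replicate 2 or 3. For Il13, lower with ADM2 alone and not called with IL-25 present, the difference was 0.75 ± 0.13 (edgeR adjusted p = 0.0881), not past the threshold. It passed with DESeq2 (adjusted p = 7.36e-05), upper-quartile factors (0.0458) and no filter on low counts (0.0215), as did Il17rb with DESeq2 (0.0271). By edgeR the differences of Il5 (−0.43 ± 0.14), Il17rb (0.49 ± 0.13), Calcrl (−0.19 ± 0.21) and Ramp1 (0.49 ± 0.35) did not pass (edgeR adjusted p from 0.470 to 0.916). Areg (−0.06 ± 0.16), Ramp3 (0.06 ± 0.14), Crem (−0.18 ± 0.16), Il1rl1 (−0.22 ± 0.11), Gata3 (0.11 ± 0.19) and Nr4a1 (0.12 ± 0.16) had differences on the log2 scale that did not pass the test (edgeR adjusted p from 0.737 to 0.971). Of 20 lists, cholesterol synthesis was called as lower in the difference (median −0.23; camera adjusted p = 2.33e-04; adjusted p = 0.396 with an estimated correlation), with 0 members called up and 0 down, or 0 and 5 adjusted over the list alone.

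**Figure D3:**
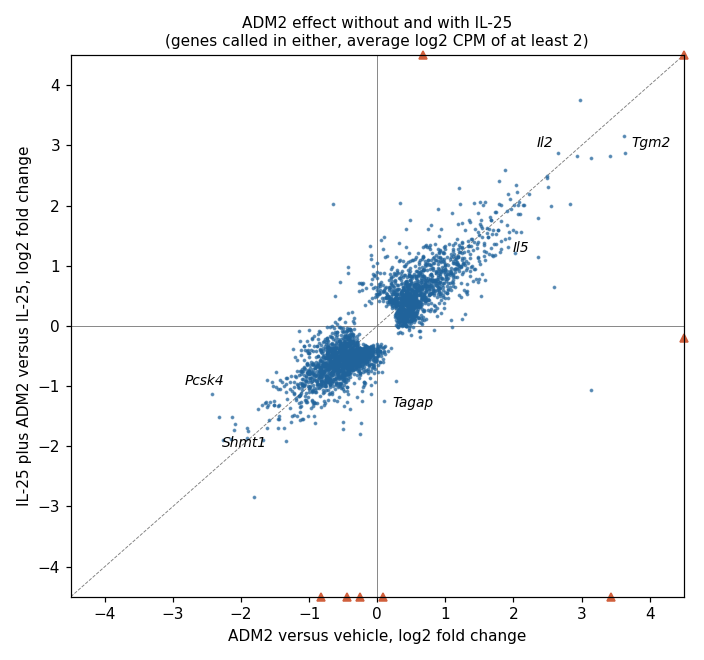
Log2 fold change of ADM2 versus vehicle (horizontal axis) against IL-25 plus ADM2 versus IL-25 (vertical axis) for the 2840 genes called in either comparison with an average of at least 2 log2 CPM, with 1 point per gene and a dashed line of equal effect. Triangles at the edge stand for 8 genes beyond a log2 fold change of 4.5 on either axis. Tgm2 lies at 3.64 and 2.87.

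ADM2 and IL-25 acted on some of the same genes, often in opposite directions. Among genes called in both comparisons against vehicle, 315 rose in both (143.9 for independent lists), 143 fell in both (115.6), 155 rose with ADM2 and fell with IL-25 (115.03), and 436 fell with ADM2 and rose with IL-25 (144.6). Rrp12, for example, was at 116 ± 5.26 CPM in vehicle, 42.1 ± 7.35 with ADM2, 196 ± 26.9 with IL-25 and 77.8 ± 5.57 with both. Groups with no effect, simulated 20 times against the shared vehicle libraries, gave at most 1 gene in any of these classes, which is chance with no effect and leaves out how shared controls act on genes that did change. The covariance of the fold changes was 0.284 against a simulated mean of 0.261 (0.239 to 0.285), and r was 0.29 against 0.50. The 3 vehicle libraries cannot be split so that each comparison keeps at least 2 controls of its own, and no split was tested, so part of the excess of genes called in the same direction may come from the shared controls. Genes called in opposite directions numbered 591, and 378 without vehicle replicate 3. Those called in the same direction numbered 458, and 291 without vehicle replicate 1 or 305 without vehicle replicate 3.

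Markers of other cells that a sort of intestinal lymphocytes can hold were measured alongside. ILC3 markers were called higher with IL-25, where 3 of 10 members rose and 0 fell, or 4 and 0 adjusted over the list alone (camera adjusted p = 2.69e-06, or 0.0183 with an estimated correlation). Il17f, Il22 and Il17a were the members that rose, which activated lymphocytes of other kinds also express. In ADM2 versus vehicle 4 of 10 members rose and 1 fell, or 4 and 2 adjusted over the list alone (camera adjusted p = 0.102). In IL-25 plus ADM2 versus IL-25 3 of 10 members rose and 1 fell, or 3 and 1 adjusted over the list alone (camera adjusted p = 0.137). The list was called higher also in IL-25 plus ADM2 versus vehicle, where 4 of 10 members rose and 1 fell, or 4 and 1 adjusted over the list alone (camera adjusted p = 2.53e-08, or 0.00802 with an estimated correlation). Lists of T cell, NK cell and ILC1, B and plasma cell, macrophage, monocyte and dendritic cell, colon epithelial, and stromal and endothelial markers were not called with ADM2 alone (camera adjusted p from 0.138 to 0.887), IL-25 alone (0.112 to 0.888), ADM2 added to IL-25 (0.0769 to 0.345) or both against vehicle (0.0798 to 0.839). Single members changed with ADM2 alone: Gzmb (1.32 ± 0.11) and Cd14 (1.65 ± 0.31) rose, and Epcam fell from 168 ± 16.0 to 80.9 ± 1.61 CPM. Trbc1, a T cell receptor gene, and Gzma were also called higher and Pecam1 lower. With the replicate block the calls of Trbc1 (edgeR adjusted p = 0.0782) and Gzma (0.0726) were lost, and that of Pecam1 without vehicle replicate 3 (0.0648). Mast cell, basophil and eosinophil markers and neutrophil markers had 2 tested members each, too few for a set test.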

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

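The tests of immunoglobulin segments were chosen after the results were seen. A test of the difference between the ADM2 effect with IL-25 and without it picked out 5 genes and 2 lists. Tagap fell with ADM2 in the presence of IL-25 (difference −1.35 ± 0.19 on the log2 scale, SE; edgeR adjusted p = 0.0293), from 82.5 ± 4.04 to 34.8 ± 1.01 CPM, and was at 20.6 ± 3.07 and 22.2 ± 2.43 CPM without it. Dnah12 fell in both settings, further with IL-25 (difference −1.03 ± 0.16; edgeR adjusted p = 0.0460). The call of Tagap was lost without vehicle replicate 1, ADM2 replicate 2 or 3, IL-25 replicate 2 or 3, or IL-25 plus ADM2 replicate 2 or 3 (edgeR adjusted p from 0.0618 to 0.271), and with the replicate block (0.0915). That of Dnah12 was lost with any of the 11 left out (from 0.0563 to 0.316). With every library kept it was lost with limma voom (adjusted p = 0.181), sample quality weights (0.110), median-ratio (0.0585) or upper-quartile factors (0.101), a minimum count of 30 (0.0531) and the replicate block (0.211). Without IL-25 replicate 2 or 3 none of these calls remained, where edgeR made 0 calls (1028 at an unadjusted p below 0.05 with every library, and 47 by DESeq2 with every library). The cholesterol synthesis list was lower in the difference (median −0.23; adjusted p = 0.396 with an estimated correlation). The T cell list was higher (median 0.50; camera adjusted p = 1.70e-04; adjusted p = 0.0209 with an estimated correlation), with 0 of 12 members called up, or 2 adjusted over the list alone. Trbc1, a T cell receptor gene of that list, was at 215 ± 20.1, 273 ± 19.3, 149 ± 15.8 and 274 ± 29.7 CPM in the vehicle, ADM2, IL-25 and IL-25 plus ADM2 groups.

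A further 2 genes were immunoglobulin segments whose levels differed between groups. Ighv1-19 (fitted difference 8.13) averaged 6.25 ± 1.41, 9.91 ± 3.87, 0.0103 ± 0.0178 and 6.89 ± 5.64 CPM in the same order, and Igkv17-127 (fitted difference −15.34) 1.08 ± 1.73, 11.8 ± 6.67 and 15.1 ± 0.761 CPM and 0 in both IL-25 plus ADM2 libraries. Fitted differences with libraries at or near 0 are not bounds. Libraries agreed closely in some groups, such as IL-25 (14.4 to 15.9 CPM of Igkv17-127 and at most 0.0309 of Ighv1-19). In others they did not, such as ADM2 (6.15 to 19.1 CPM of Igkv17-127) and IL-25 plus ADM2 (2.90 to 10.9 CPM of Ighv1-19). Whether libraries of a group shared source cells was not tested. Over 155 V segments with at least 200 counts, the highest library held a median of 0.280 of a segment's scaled counts, against 11.97% for Jchain, 12.02% for Igha and 12.4% for Igkc, where even shares would be 9.09%. RNA of a few plasma cells of different clones in each library was set to need over 0.3. Free plasma cell RNA from 1 shared pool was set to need under 0.2. The value of 0.280 lies between, so this test cannot tell the explanations apart. Segments shared by the libraries of 1 group, as Igkv17-127 was with IL-25, were a case that the limits left out. They can also raise the highest share, so a share over 0.3 would not have shown different clones in each library. Igha (1724 to 3232 CPM) and Jchain (247 to 479 CPM) were present in each of the 11 libraries. Lineage-negative sorting would remove plasma cells, but the gates are not described in the labels, and no biological explanation was tested.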

How the results depend on the processing

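The fits without immunoglobulin genes were chosen after the data were seen. Of 7673 values of 405 named results under other settings and with 1 library left out, 7421 stayed on the same side of the threshold, 193 lost the call, 59 gained one and 0 changed sign with a call in either fit. Among the 7421 were 39 that changed sign and were called in neither fit. Fits of only the groups compared were not part of these values. Those fits called 2414 genes in ADM2 versus vehicle, 3036 in IL-25 versus vehicle and 2924 in IL-25 plus ADM2 versus vehicle. In IL-25 plus ADM2 versus IL-25 they called 1489, against 2198 with all 11 libraries, and 1456 were shared. Leaving out either library of the IL-25 plus ADM2 group leaves 1, which is then assumed to vary like the other groups.

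Requiring a change of at least 2-fold left 481 genes of 2227 in ADM2 versus vehicle, 672 of 3503 in IL-25 versus vehicle, 499 of 2198 in IL-25 plus ADM2 versus IL-25, 835 of 3042 in IL-25 plus ADM2 versus vehicle and 570 of 3708 for the averaged ADM2 effect, by construction. With 1 library left out these counts ran from 1597 to 2551, 2522 to 3474, 1275 to 2255, 1695 to 3426 and 2969 to 3810. IL-25 plus ADM2 versus IL-25 fell to 1323 without replicate 2 and 1275 without replicate 3 of IL-25 plus ADM2, and IL-25 plus ADM2 versus vehicle to 1695 without replicate 3, with fewer samples.

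The difference of the ADM2 effect had 5 calls by edgeR (1028 at an unadjusted p below 0.05), 47 with DESeq2, 1 with limma voom and 2 with sample quality weights. There were 47 with no filter on low counts, 3 with a minimum count of 30, 2 with the replicate block and 2 without immunoglobulin genes. It had from 0 (without IL-25 replicate 2 or 3) to 6 with 1 library left out. The cause was not tested.

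An estimated correlation lowered the lists called from 14 to 7 for ADM2 versus vehicle, 11 to 4 for IL-25 versus vehicle, 13 to 6 for IL-25 plus ADM2 versus IL-25, 16 to 10 for IL-25 plus ADM2 versus vehicle, 14 to 6 for the averaged effect and 1 to 0 for the difference. For the difference fry also called 0. The estimated correlation widens the spread expected of correlated genes. With 1 library left out the lists called ran from 12 to 14, 10 to 12, 13 to 14, 15 to 17, 13 to 15 and 1 to 6 in that order. The difference had 6 without ADM2 replicate 2 or IL-25 plus ADM2 replicate 3, 4 without vehicle replicate 2 or IL-25 replicate 2, 3 without IL-25 replicate 1 and 2 without vehicle replicate 3. The cause was not tested.

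The share of genes called in ADM2 versus vehicle that had the same sign with IL-25 was 97.9%, 96.3% with DESeq2, 96.7% with limma voom and 96.5% to 98.8% with 1 library left out. The 95% interval of 97.3% to 98.5% takes genes as independent, which they are not, so it is too narrow, and the values with DESeq2 and limma voom lie below it. The cause was not tested. Genes called in both comparisons against vehicle numbered 591 in opposite directions (378 to 630 with 1 library left out, 378 without vehicle replicate 3) and 458 in the same direction (291 to 469, with 291 without vehicle replicate 1 and 305 without vehicle replicate 3).

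Scaling by total counts moved the median of all genes in ADM2 versus vehicle by −0.13. Samples of the same replicate number had correlations of −0.07 to 0.07 after group means were removed (15 pairs), and those of other numbers −0.07 to 0.07 (30 pairs). No pairing by number was seen. Deviations within a group sum to 0, which ties these ranges to each other, so a shared sort or pool cannot be excluded. With the number as a block 1853, 3050, 1653, 2456 and 3232 genes were called in the order above. Depth was 25809256 to 35445351 counts per library, and in simulated data 32.8% of 2-fold differences of the ADM2 effect were recovered, so that a missing call there does not show equal effects.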

Other observations

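The tests of nucleotide synthesis, Il17a and Il17f were chosen after the results were seen, and those of other splits before. The tests of MYC genes are recorded as set before, but they name that list and its direction in both ADM2 comparisons. They therefore follow up a result and are not independent of it. Besides ribosome biogenesis, ADM2 lowered genes that make nucleotides and the 1-carbon units these need. A list of 31 such genes, written after several had been seen among the largest decreases, had 0 members up and 21 down with ADM2 alone, 24 up and 0 down with IL-25 alone, and 0 up and 25 down when ADM2 was added to IL-25. Its members Gart (−1.42 ± 0.11 with ADM2 alone), Mthfd1 (−1.25 ± 0.09), Dhodh (−1.20 ± 0.16) and Cad (−1.11 ± 0.14) were named after their values were seen. They encode steps of nucleotide synthesis or of the supply of its 1-carbon units. Over the 24 members outside the fixed lists and the named genes, the median log2 fold change was −0.46, 0.50 and −0.75 in the same order, and the higher of the camera p-values with an estimated correlation for ADM2 was 9.30e-04. A candidate explanation is that ADM2 lowers transcripts of this biosynthesis, without IL-25 as well as with it. It was found and tested on the same 11 libraries, and cell growth was not measured. In IL-25 plus ADM2 versus vehicle 3 of the 31 members rose and 9 fell. In the difference of the ADM2 effect 0 were called either way (camera p = 0.0829 with an estimated correlation, or 0.0384 over the 24 members). Neither the fall with ADM2 nor the rise with IL-25 covered every member. With IL-25 alone Gart (0.35 ± 0.11) and Mthfd1 (0.62 ± 0.09) rose. Dhodh (−0.15 ± 0.16; edgeR adjusted p = 0.561) and Cad (0.25 ± 0.14; 0.225) were not called there.

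The lower MYC and ribosome biogenesis genes were set against scaling and sequence bias. Over 4 scalings and both ADM2 comparisons the list median nearest to 0 was −0.605 on the log2 scale, which argues against scaling between libraries. After the trend with GC content and transcript length was removed over 14314 genes, with values for 26 of 26 members, the median nearest to 0 was −0.675, which argues against such a bias. RNA from other cell types and the mix of cells in each culture were not tested for this list, so a biological explanation may hold but stays a hypothesis.

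Il17a and Il17f, which ILC3s and some T cells make, rose with either stimulus, Il17f by 2.56 with ADM2 and 3.63 with IL-25 on the log2 scale. For T cell RNA the upper quartile of 12 T cell markers was at most 0.214 against vehicle. This argues against a general rise of T cell RNA there. The marker median was −0.17 with ADM2 and −0.54 with IL-25, and the highest marker 1.16 and 1.11. Trbc1 was called higher with ADM2 alone. T cells already in the cultures that switched on Il17a and Il17f need not move these markers, so they cannot be excluded in either comparison. When ADM2 was added to IL-25 the upper quartile was 1.21. More T cell RNA and a response of the sorted cells therefore cannot be told apart in that comparison. Sorting gates that would remove T cells are not described in the labels.

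Other splits of the libraries were counted for the comparisons with at least 3 libraries per group. For ADM2 versus vehicle (2227 calls) the highest of the other splits gave 0, and for IL-25 versus vehicle (3503 calls) it gave 1, but 10 splits are too few for a share under 0.05 (1 in each, the real one). For the averaged ADM2 effect 1 of 100 drawn regroupings, the real one, gave as many as 3708 calls, a share under 0.05. Most regroupings mix libraries with and without ADM2 in 1 group, so an effect of ADM2 widens their spread and lowers their calls. The share shows that the calls go with the labelled groups, but cannot exclude another difference between those cultures. The highest of the other regroupings gave 1975, and it kept 0 of the true ADM2 libraries in either background under that name, so it is nearly the mirror image of the real split.

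Each of the 11 libraries held both Xist (99.2 to 184 CPM) and the Y-linked Ddx3y (105 to 209 CPM), and the labels do not say whether libraries pool mice of both sexes. Ddx3y was at 112 ± 8.08, 167 ± 8.44, 145 ± 10.3 and 209 ± 0.376 CPM in the vehicle, ADM2, IL-25 and IL-25 plus ADM2 groups, with no overlap between groups. Xist was at 148 ± 42.3, 168 ± 16.2, 147 ± 15.1 and 164 ± 24.6 CPM in that order, with overlap between groups. In the same order the Y-linked genes Uty, Eif2s3y and Kdm5d, whose groups overlapped in part, were at 18.2 ± 2.30, 26.2 ± 3.17, 19.8 ± 1.27 and 25.8 ± 1.51 CPM, 58.1 ± 6.38, 74.1 ± 3.43, 63.7 ± 9.41 and 70.1 ± 12.8 CPM, and 27.6 ± 4.31, 28.2 ± 2.89, 23.8 ± 5.22 and 24.7 ± 3.39 CPM. The genes of this paragraph were named after their values were seen, and a difference between groups in the share of male cells was not tested.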
